A study of Phaseolus coccineus with 4 samples.

How the data were processed

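Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on scarlet runner bean (Phaseolus coccineus, cultivar Hammond's Dwarf Red Flower) with an antibody raised against a peptide of WOX9-like, a homeodomain transcription factor of the WUSCHEL-related homeobox family. Per the labels' protocols, plants grew at 22 degrees Celsius with 16 h of light and 8 h of dark. Seeds of 1.6 to 2.5 mm were taken 6 days after hand pollination, when embryos were globular. Only the micropylar part, the end of the seed that holds the embryo, was crosslinked, for 10 min in 1% formaldehyde. Chromatin was sheared to 100 to 500 bp and incubated with 10 ug of antibody. Libraries were amplified with 15 PCR cycles, and no molecular identifiers are mentioned. The series holds 4 samples, 2 of WOX9-like ChIP and 2 of input chromatin. The labels number the replicates but do not say that they came from separate plants or days, so differences between them measure the spread between these samples, which may be technical.

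One peak list per ChIP replicate was analysed. Bowtie 0.12.7, SAMtools 0.1.18 and MACS2 are named in the submitters' processing notes, without settings, and the MACS2 version is not given in the sources used here. Peaks were called separately in each sample, as the 2 deposited lists show. Each list gives, as deposited by the authors, the fold enrichment of the summit over the control (a ratio), its p-value and its q-value as −log10, a whole-number score, and the summit's position. The score in the deposited lists was the whole part of 10 times −log10 q for 99.97% of replicate 1 peaks and all replicate 2 peaks. The lowest deposited −log10 q was 2.00 in replicate 1 and 2.03 in replicate 2, next to a q-value threshold of 0.01. Per the deposited peak names, the control of replicate 1 was called noAb and the run label named several runs, whereas the control of replicate 2 was called input and 1 run was named. Whether these controls are the 2 input samples of the series was not settled, so fold enrichments of the 2 lists may rest on controls of different kinds. The peak names end in Pv442, and the sequences are 11 numbered chromosomes and numbered scaffolds. The build is not stated in words. The tag is read here as an assembly of common bean (Phaseolus vulgaris), a related species, in which case reads of one species were placed on the genome of another and diverged sequence would be under-represented. The gene table at hand belongs to a Phaseolus coccineus assembly and was not used. The planned analyses of gene location, upstream genes, fixed gene lists and sequence motifs need the sequence and annotation of the files' build and were not run. Regions are therefore given by position, counted from 1.

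No interval was listed more than once in a list. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1). The shared number was compared with 1000 random placements of replicate 2's peaks, with their widths, on the same sequences within the span of both lists (one-sided permutation test, smallest possible p 0.001). Overlapping peaks of both lists were then merged into regions, each with the highest-fold peak of each replicate. Shares carry 95% Wilson intervals. Correlations are across regions, which are not independent replicates, with intervals from 200 resamples of the regions. The regions named were fixed by rule before the data were examined: with no annotation of the build, the 10 shared regions with the highest lower-of-2 fold enrichment. Other peaks named singly (the highest-fold, widest and strongest unshared peaks, and the densest 1 Mb bins) were chosen after their values were seen, as was the analysis of position along the chromosomes. For the latter, the outer parts of a chromosome are the 25% of its span at each end, and chromosome length was taken as the span to the last peak.

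Library sizes are not given in the lists, so total depth is unknown. The number of ChIP fragments behind each summit could be computed, because MACS2 writes fold as (pileup + 1)/(background + 1) and p as a Poisson tail of the same 2 values. Whole fragment counts fitted both deposited values to within 0.002 in −log10 p for 99.99% of replicate 1 peaks, with ChIP counts multiplied by 0.99444, and for all replicate 2 peaks with no scaling of the ChIP. In replicate 2, 79.6% of the backgrounds were whole multiples of 0.859 (within 0.02 of a step), as for a control larger than the ChIP library and scaled down, and the others lay between the steps. Exact 95% Poisson intervals of these counts are given for single peaks. They cover counting error of the ChIP fragments only, and PCR reads without molecular identifiers are not independent molecules. The overlap count, placement test and count computation were tested on simulated data. Of 9000 simulated peaks, 6000 of them copies of replicate 1 peaks, 6224 overlapped replicate 1, and all simulated summit counts were recovered. Of 40 unrelated simulated lists, 2 gave a placement p at or below 0.05. Those lists were placed uniformly, as in the test itself. They lacked the uneven density of the real lists along the chromosomes, so this check does not cover lists that share such a density.

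Alternatives were a −log10 q of at least 5, a fold of at least 5, overlap of at least 50% of both peaks, summits within 100 bp, lists of equal length, circular shifts as placements, and ranking by q-value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.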

Results

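The study profiled chromatin enriched by ChIP of the WOX9-like protein in the micropylar end of the seed at the globular embryo stage. WOX9 proteins are homeodomain transcription factors known from Arabidopsis for their role in the basal lineage of the early embryo. Both ChIP replicates gave a peak list, called by the authors against a control library, so enrichment over control is already contained in every fold value. The input samples were not analysed here as samples of their own. No second tissue, stage or genotype was profiled in these samples. The comparison that the design allows is that between replicates, which asks which enriched regions were found in both. Whether a peak marks binding by the WOX9-like protein was not tested here.

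The list of replicate 1 held 34876 peaks covering 18.03 Mb, and that of replicate 2 held 23218 peaks covering 10.1 Mb. Peaks were narrow in both, with a median width of 406 bp (quartiles 292 and 603 bp) in replicate 1 and 352 bp (quartiles 254 and 518 bp) in replicate 2. The median fold enrichment was 4.36 in replicate 1 and 5.08 in replicate 2. A fold of at least 10 was reached by 3151 peaks of replicate 1 and 3167 peaks of replicate 2. Almost all peaks lay on the 11 chromosomes, and 1.38% of replicate 1 peaks and 1.42% of replicate 2 peaks lay on unplaced scaffolds. The summit of the median peak was covered by 76 ChIP fragments in replicate 1 and 44 in replicate 2. The median local backgrounds were 17.0 and 8.60, the latter in control fragments multiplied by 0.859.

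Most peaks of replicate 2 overlapped a peak of replicate 1. Of the 23218 peaks of replicate 2, 22344 (96.2%, interval 96.0 to 96.5) overlapped a replicate 1 peak, whereas 20922 of the 34876 peaks of replicate 1 (59.99%, interval 59.5 to 60.5) had a partner in replicate 2. Random placement gave a mean of 1613 overlapping replicate 2 peaks and at most 1736, and a mean of 1630 overlapping replicate 1 peaks, so the observed numbers were 13.9 and 12.8 times those of chance (one-sided permutation test, p = 0.001 for both, the smallest that 1000 placements can give). Merging gave 20728 regions present in both lists, 13954 in replicate 1 alone and 874 in replicate 2 alone. Requiring overlap of at least 50% of both peaks left 49.2% of replicate 1 peaks and 73.8% of replicate 2 peaks with a partner. With lists of equal length, 79.5% of the replicate 1 peaks and 85.9% of the replicate 2 peaks had a partner.

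The strongest peaks were nearly all found in both replicates. In the top decile of replicate 1 peaks by fold (9.73 to 30.2), 98.3% had a partner, against 19.1% in the lowest decile (fold 1.30 to 2.55). In replicate 2 the corresponding shares were 99.96% and 88.2%. Replicate 1 peaks with a partner had a median fold of 5.80 and a median width of 524 bp, and those without one had 3.18 and 293 bp.

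**Figure D1:**
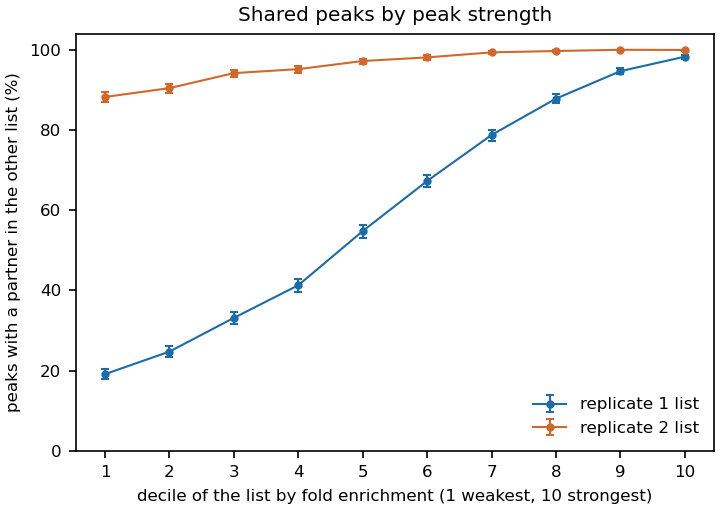
Share of peaks with a partner in the other list (vertical axis, percent) in each decile of a list ranked by fold enrichment (horizontal axis), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. The share in replicate 1 runs from 19.1% in the lowest decile to 98.3% in the top decile, and that in replicate 2 from 88.2% to 99.96%.

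Summits fell at nearly the same base pairs in both replicates. The median distance between the 2 summits of a shared region was 36 bp, and 85.0% lay within 100 bp. In the 1819 shared regions with a fold of at least 10 in both replicates, the median distance was 26 bp. Fold enrichment at shared regions was correlated between replicates (Spearman rho 0.71, interval 0.70 to 0.72, and Pearson r of log2 fold 0.71, across 20728 regions). The median log2 ratio of replicate 2 to replicate 1 was −0.06 with an SD of 0.54 across regions, and 93.3% of regions differed by no more than 2-fold. Counting of ChIP fragments alone would give an SD of 0.26 in the median region. After centring, 36.2% of regions differed by more than ChIP counting error and 2.56% by more than the counting error of ChIP and control together, where 5% are expected. The control part of that error takes each background as a single count of fragments. Only 69.7% of replicate 1 and 79.6% of replicate 2 backgrounds were whole steps of such a count. That error may therefore be too large, and the low share does not show that counting noise accounts for the differences.

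**Figure D2:**
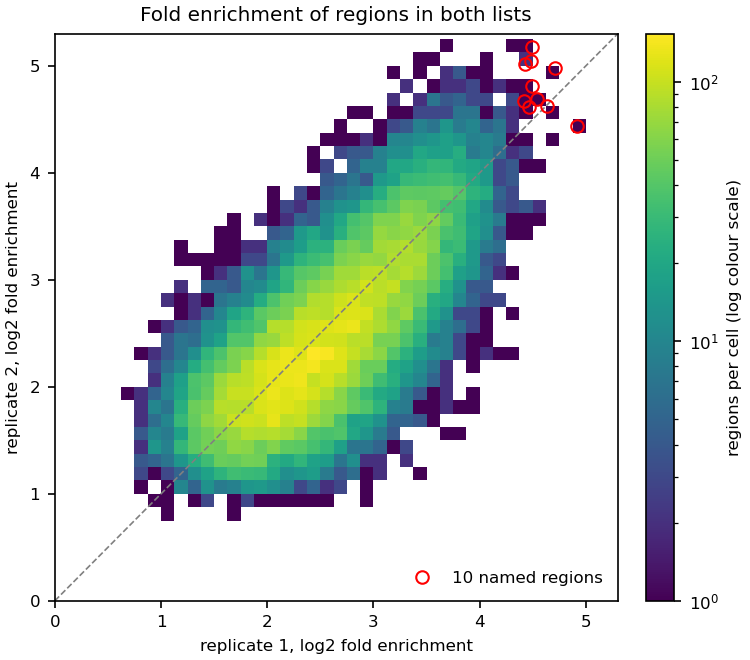
Log2 fold enrichment over control in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for the 20728 regions in both lists; colour gives the number of regions per cell on a log scale, the dashed line marks equal values and red circles mark the 10 named regions. Regions lie along the line of equal values, with Spearman rho 0.71.

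Across each list, fold was lower where the local background was higher (rho −0.25 in replicate 1 and −0.31 in replicate 2). Ranking by fold therefore also favours low control backgrounds. The replicate 1 backgrounds of the 10 named regions were at most 14.2, against a list median of 17.0. Those of replicate 2 were below its median of 8.60 at all but the chromosome 5 region. By the lower of the 2 folds, the highest region lay on chromosome 4 from 5003944 to 5004550. Its fold enrichment was 28.8 ± 3.78 (SD, n = 2), with 262 ChIP fragments at the summit in replicate 1 and 193 in replicate 2 and summits 2 bp apart. A 1651 bp region on chromosome 7, from 24705933 to 24707583, had a fold of 24.7 ± 0.168 (SD, n = 2), the closest match between replicates among the 10. A region on chromosome 6, from 18300873 to 18302459, had a fold of 24.5 ± 1.82 (SD, n = 2), and one on chromosome 10, from 4417319 to 4417864, had 23.3 ± 1.68 (SD, n = 2). On chromosome 8 the region from 14775577 to 14776303 had a fold of 25.2 ± 3.91 (SD, n = 2), and on chromosome 1 the region from 40806241 to 40807403 had 23.4 ± 2.96 (SD, n = 2).

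The other 4 regions of the rule differed between replicates by more than ChIP counting error, as their exact Poisson intervals did not overlap. Overlap of the intervals at the 6 regions above does not show that those agree within that error. This is another criterion than that behind the share of all regions given earlier, which tested the ratio itself. The Poisson intervals leave out the counting error of the control. Whether the 4 regions differ by more than both errors together is not given here. The region on chromosome 2 from 10138483 to 10139177 had a fold of 22.5 (interval 19.9 to 25.4) in replicate 1 and 36.2 (interval 31.3 to 41.7) in replicate 2, the highest fold of that list. Its mean, 29.4 ± 9.68 (SD, n = 2), was the highest of the 10. The region on chromosome 7 from 2597291 to 2598255 had 22.3 (interval 19.9 to 24.9) and 33.1 (interval 28.9 to 37.6). The widest of the 10 regions, 2318 bp on chromosome 8 from 1614276 to 1616593, had 21.5 (interval 19.2 to 24.0) and 32.4 (interval 28.4 to 36.7). The region on chromosome 5 from 39863245 to 39863985 differed in the other direction, with 30.2 (interval 26.8 to 33.9) in replicate 1, the highest fold of that list, and 21.7 (interval 19.1 to 24.6) in replicate 2. Its summits held 280 and 245 ChIP fragments over backgrounds of 8.25 and 10.3. Shared regions of fold 5 or more in both had 0.496 times the fragments in replicate 2, so its fragments were not low there. The reversed fold goes with the control backgrounds. The 8.25 of replicate 1 was near that list's lowest value of 7.43 and below its median of 17.0. The 10.3 of replicate 2 was above that list's median of 8.60. At the others of these 4 the background was lower in replicate 2. Both backgrounds rest on few control fragments, so counting noise of the control may account for their difference. All 10 regions had summits within 50 bp of each other. By geometric mean fold, 8 of the 10 would again be among the highest 10, and by the lower −log10 q, 4 would be. Genes at these positions were not analysed here.

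**Figure D3:**
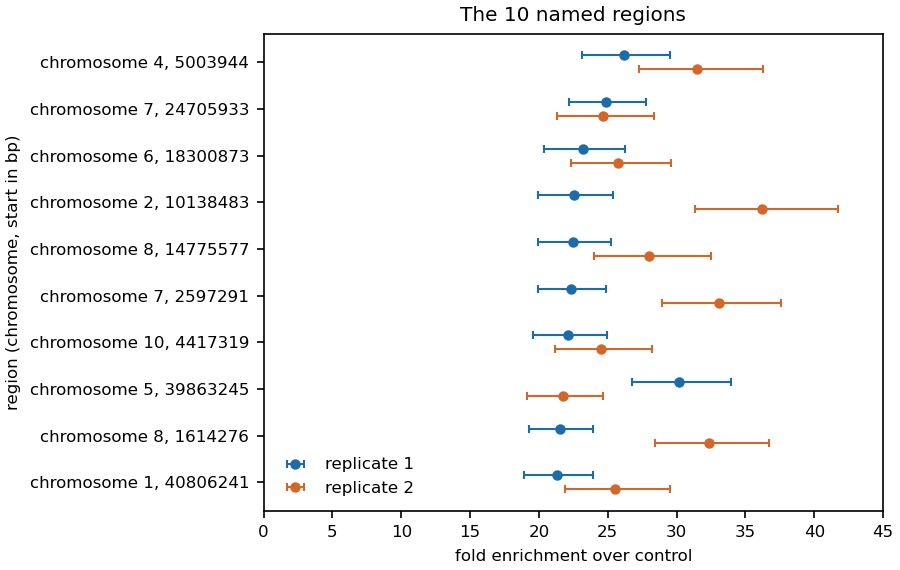
Fold enrichment over control (horizontal axis) of the 10 named regions (vertical axis, chromosome and start) in replicate 1 (blue) and replicate 2 (orange), with bars for the exact 95% Poisson interval of the ChIP fragment count. The intervals of 4 regions do not overlap between replicates, and 3 of these are higher in replicate 2.

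Some peaks of high fold were found in a single replicate. The list of replicate 1 held 52 peaks of fold 10 or more without a partner, and that of replicate 2 held 1. The strongest of replicate 1 lay on chromosome 11 from 18066375 to 18066836, with a fold of 14.6 (interval 12.4 to 17.2), 146 fragments and the nearest replicate 2 peak 3237 bp away. The next lay on chromosome 8 from 16772072 to 16772487, with 14.5 (interval 12.1 to 17.3), and on chromosome 10 from 10364755 to 10365332, with 14.1 (interval 11.9 to 16.6). The single such peak of replicate 2 lay on chromosome 11 from 2616168 to 2616490, with a fold of 12.1 (interval 9.70 to 15.0), and the nearest replicate 1 peak was 682 bp away. Its background was 5.92, against a median of 8.60 over the replicate 2 list.

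The widest peaks of replicate 1 overlapped several peaks of replicate 2. The widest of replicate 1 spanned 6073 bp on chromosome 4 from 46841894 to 46847966, with a fold of 5.20, and overlapped 7 peaks of replicate 2. A peak of 5836 bp on chromosome 2 from 1228145 to 1233980 reached a fold of 13.5 and overlapped 3 peaks of replicate 2. In replicate 2 the widest peak spanned 4259 bp on chromosome 9 from 8247080 to 8251338, with a fold of 5.65, and a peak of 4091 bp on chromosome 5 from 37474043 to 37478133 reached 16.1. Each of these 2 peaks overlapped 1 peak of replicate 1. In all, 1322 shared regions joined several replicate 2 peaks under 1 replicate 1 peak, and 129 the reverse.

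Shared regions were denser toward the chromosome ends than in the middle on 10 of the 11 chromosomes. The outer parts (25% of the span at each end) held 14122 of 20433 shared regions (69.1%, interval 60.3 to 77.9 with chromosomes resampled), against 50% for uniform positions. The highest share in 1000 uniform random draws was 51.0% (one-sided permutation test, p = 0.001, the smallest possible). Shared regions were clustered (variance over mean 27.1 per 1 Mb bin), which this p leaves out of account. The interval over chromosomes is the better guide to the spread. The share was 86.6% on chromosome 8, 82.8% on chromosome 10, 82.2% on chromosome 4 and 82.0% on chromosome 11. It was 56.3% on chromosome 6, where shared regions were densest at the far end alone, and 40.5% on chromosome 9. Chromosome 9 had the highest density, 61.7 shared regions per Mb, and chromosome 4 the lowest, 23.6 per Mb. The densest 1 Mb bin was on chromosome 6 from 28 to 29 Mb, with 147 shared regions, followed by chromosome 3 from 46 to 47 Mb with 132, chromosome 7 from 2 to 3 Mb with 131 and chromosome 2 from 1 to 2 Mb with 127. The median bin held 29.5, and 114 of 510 whole bins held 10 or fewer. The longest stretch without a shared region was 3.13 Mb on chromosome 11, from 38369251 to 41501224. Peaks per bin were correlated between replicates (Spearman rho 0.99, Pearson r 0.99, across 510 bins). Strength was similar in the outer parts and the middle: the median lower-of-2 fold was 4.73 and 4.78. Of the 200 strongest shared regions 70.0% lay in the outer parts, against 69.1% of all. Fold was not compared with density per bin. How much of each bin could be mapped is unknown.

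**Figure D4:**
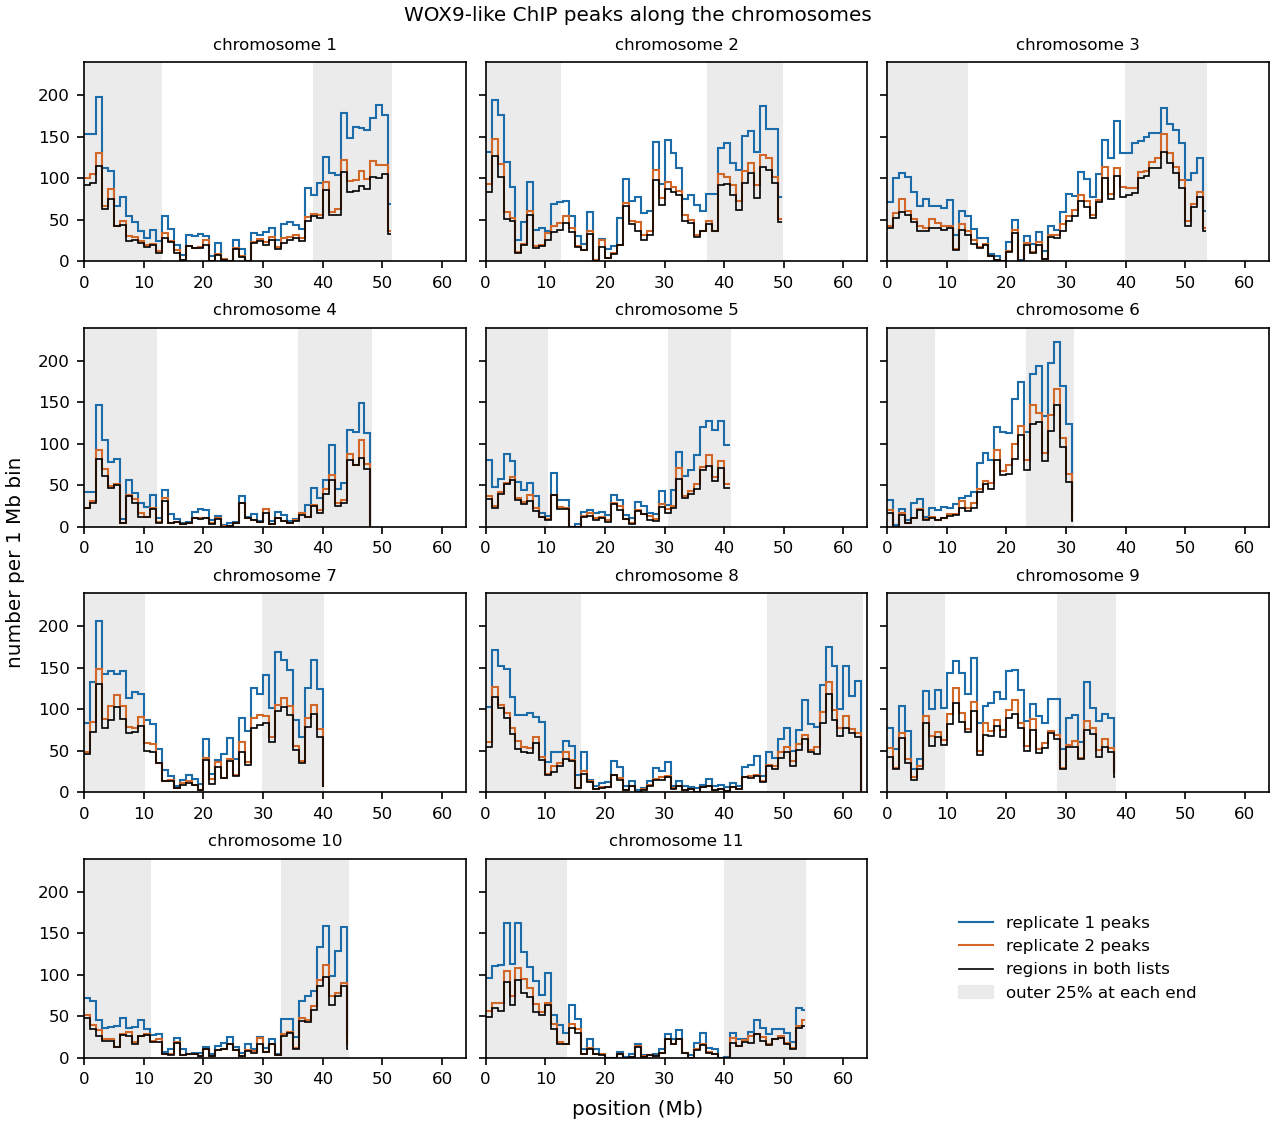
Number of peaks of replicate 1 (blue), of replicate 2 (orange) and of regions in both lists (black) per 1 Mb bin (vertical axis) along the 11 chromosomes (horizontal axis, Mb); grey marks the outer 25% of the span at each end, and the last bin of each chromosome is shorter. Counts are low in the middle of most chromosomes, whereas chromosome 9 shows no such trough and chromosome 6 rises to 147 shared regions from 28 to 29 Mb.

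The replicates were spread over the chromosomes in similar proportions, with 1.45 (chromosome 3) to 1.58 (chromosome 5) replicate 1 peaks per replicate 2 peak. The share of replicate 1 peaks with a partner was between 57.2% on chromosome 5 and 63.0% on chromosome 3, and that of replicate 2 peaks between 95.4% on chromosome 6 and 96.9% on chromosome 2. Scaffold 15 held 78 shared regions, scaffold 17 held 49 and scaffold 30 held 34, out of 295 on all scaffolds.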

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

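The tests of position along the chromosomes, local placement, chromosomes without scaffolds, single-peak regions and fragment counts were chosen after seeing the data. Of 34 alternative values, 21 stayed within the limits set (1.5 times, for a count) and none changed direction. The rule of overlap moved the shared shares within these limits: overlap of at least 50% of both peaks gave 49.2% in replicate 1 and 73.8% in replicate 2, and summits within 100 bp gave 51.3% and 76.98%. The excess of shared peaks over chance gave a permutation p of 0.001 again with circular shifts and with local placement by 20 to 500 kb, which raised the chance number to 2309 replicate 2 peaks. A fold of at least 5 left 14282 peaks in replicate 1 and 11887 in replicate 2, of which 9586 and 10007 had a partner. Requiring this in both lists also removes partners just under the limit. Spearman rho of fold was 0.69 with −log10 q of at least 5, 0.55 with a fold of at least 5 (a narrower range of values), 0.72 with summits within 100 bp, 0.70 for regions with 1 peak in each list, and 0.84 for summit fragment counts in place of fold. Ranking by q-value changed the shared share of the lowest decile to 13.6% in replicate 1 and 83.9% in replicate 2, and that of the top decile to 99.7% and 100%. The share of regions in the outer parts of the chromosomes was 69.1% to 69.2% when either replicate was left out. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no values here. The alternatives set beforehand for gene location, upstream genes, gene lists and motifs were not run, for want of the files' build. Total depth is unknown. The precision of a fold rests in part on the fragments at its summit, 76 in the median over the replicate 1 list and 44 over the different set of peaks in the replicate 2 list. It rests also on the control, with lower median backgrounds of 17.0 and 8.60. In replicate 2 these are control fragments multiplied by 0.859.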

Other observations

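All tests in this part were chosen after the values were seen. The summit fragment counts give a relative depth that the lists do not state. The lowest background in a list, which MACS2 takes from the genome-wide average, was 7.43 in replicate 1 and 2.87 in replicate 2, after any scaling. Per bp of the shortest peak width (198 and 185 bp, read here as the fragment length), that is a ratio of 2.42 if the same genome size was set for both.

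The first pattern is that of replicate 1 peaks missing from replicate 2. At shared regions with a fold of at least 5 in both, replicate 2 had 0.496 times the summit fragments and 0.451 times the background of replicate 1. With these factors, 11798 replicate 1 peaks would be detected in replicate 2 with a chance of at least 0.99, even at the lower 95% limit of their count and the upper limit of their background, and 402 of them (3.41%, exact interval 3.09 to 3.75) were absent. The factors rest on regions called in both lists, and with the ratio of the lowest backgrounds (0.386) for both, 158 of 9116 such peaks (1.73%, interval 1.48 to 2.02) were absent. With 0.386 for the count and 0.451 for the background, 100 of 7812 (1.28%, interval 1.04 to 1.55) were. The local background of the 402 peaks was 0.922 times that of present peaks with the same count (bootstrap interval 0.895 to 0.941), and with the background of all replicate 1 peaks of the same count 72 of the 158 and 38 of the 100 would still be predicted. How many of these absences lower depth or a low control background accounts for therefore stays open. For the 13552 absent peaks with a lower chance the role of depth cannot be told apart from that of other differences: their number was 0.947 times that predicted at the limits but 7.23 times that predicted at the central values. A difference between the 2 kinds of control at these positions, counts made too certain by PCR copies, and a difference between the seed collections stay open, and no biological explanation was tested.

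In the other direction, 9307 replicate 2 peaks would be detected in replicate 1 by the same rule, and 5 (0.0537%) were absent, under the 1% that the rule allows. The higher median fold of the whole replicate 2 list may come in part from the many weak peaks of the longer list: at shared regions the median log2 ratio of replicate 2 to replicate 1 was −0.0589, and the 23218 replicate 1 peaks with the best q-values had a median fold of 5.70. Among strong regions the ratio goes the other way, with a median of 0.11 in the 1819 shared regions of fold 10 or more in both and a higher value in replicate 2 at 8 of the 10 named regions. These regions were picked by the same folds that the ratio compares, which can itself shift the median. The named regions are among the 1819 and add no separate evidence.

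The lists give control backgrounds at peaks alone, and most were above the lowest value of their list. The local background at replicate 1 peaks was 2.29 times the lowest background in the median, and that at replicate 2 peaks 3.00 times, and 0.843% and 1.74% of peaks were at the lowest value. Backgrounds simulated with counting noise around the lowest value, taken over the windows that MACS2 uses by default, had medians of 1.08 and 1.18 times it, and 92.0% of replicate 1 peaks and 88.6% of replicate 2 peaks lay above the 90th percentile of the simulation, so counting noise around the lowest value does not account for the excess. A genome size set larger than the part that could be mapped would also give an excess; this was not tested, and the cause was left open.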
